A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

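The series compared yeast (Saccharomyces cerevisiae, strain S288C) exposed to 12.6 µM zinc pyrithione for 2 h with untreated yeast on 2-colour cDNA arrays. Per the labels' protocols, RNA was extracted with hot phenol, polyadenylated RNA was purified and labelled by first-strand cDNA synthesis, with Cy5 for treated and Cy3 for untreated cells. The series' design text states 3 hybridizations of independent biological samples, each scanned at 2 laser powers, so that the 6 samples were counted as 3 replicates.

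The deposited values are log ratios of both dyes, 1 column per scan. Per the labels, spots without a quality flag were used for LOWESS normalization by the authors. The values were read as log2 because both signs occur around 0 and the lowest value is the base-2 logarithm of a ratio of 0.01. Medians of the scans lay between 0.0186 and 0.0817. Which dye stands on top of the ratio is not stated; channel 1 (Cy5, treated) over channel 2 (Cy3, untreated) was taken as likely by convention. A merged value of both scans that the labels mention was not analysed here, nor were spot intensities, so that signal over background is not known and spots near background could not be marked. The version of the authors' analysis software is not given in the sources used here. LOWESS removes trends of the ratio with brightness and sets the average ratio near 0, so that a shift shared by most transcripts cannot be seen.

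Of the 6912 spots, 5446 were named by 1 gene in the platform annotation, 0 by several and 1466 by none. All 5446 were matched to the RefSeq annotation (assembly R64), used for names alone; no coordinates are given because the build behind the array is not given in the sources used here. The named spots stood for 5379 genes. For 20 genes with more than 1 spot the spots were averaged; in 6 of them the mean ratios of the spots differed in sign, and in 3 the spots held identical values in every scan, as did the 49 spots of ACT1, which appear to have been averaged before deposit. A total of 4 values lay at the lowest deposited value (log2 of -6.64), all in the high-power scan of replicate 2: PXR1, CDC7, HYM1 and an unnamed spot. There were 0 unused sample columns.

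For each array, the log2 ratios of both scans were averaged where both were present, and otherwise the one present was taken. Genes with values in all 3 replicates (4312) were tested, 5048 had values in at least 2, and 85 had none. The mean log2 ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The ratio pairs each treated culture with an untreated one on the same array. The median SD between replicates was 0.273, and the smallest log2 ratio called had a size of 0.541. The number of arrays limits the precision.

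A set of 35 gene lists was fixed before the data were examined, and the 33 with at least 3 measured genes were tested. The main list test was limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Limma's camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation. On 3 arrays the latter rests on few degrees of freedom, so that a small adjusted p is hard to reach. Counts are given over all genes and adjusted over the list alone. Lists share members. Named genes were chosen by a rule fixed at the same time: among genes past the threshold with the same sign in all replicates, the 12 highest and 12 lowest; up to 4 such members of each list, those farthest from 0; all members of the 3 iron lists; and up to 2 members, as values, of a list with none past the threshold. Both scans of an array were compared by testing their difference per gene with limma.

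The procedure was tested on 1 set of simulated values for the 4312 genes, drawn independently of each other, with known changes. Of 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale, 1.49%, 58.2% and 95.5% were recovered. Of 112 calls, 9 (8.04%) were false. The respiratory chain list, shifted by -1 in all its genes, was called by fry and by camera with a preset correlation but not with an estimated correlation (adjusted p = 0.17), and 1 of 30 unshifted lists was called by fry.

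Alternatives were the high-power or low-power scans alone, genes with both scans on all arrays, genes with at least 2 replicates, each scan centred on its median, quantile normalization, robust eBayes, limma's treat against 1.5-fold, an adjusted p under 0.01, 2-fold in every replicate without a test, and each replicate left out. Centring of blocks of spots, the unnamed spots included, and the lowest values taken as missing were added after the data were seen. Figures were drawn with matplotlib 3.10.9.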

Results

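Budding yeast of the S288C laboratory strain growing exponentially in rich medium at 25 °C was exposed for 2 h to 12.6 µM zinc pyrithione, a zinc complex used as an antifungal and antibacterial agent in anti-dandruff shampoos and antifouling paints. Messenger RNA of treated cells was labelled with Cy5 and messenger RNA of untreated cells with Cy3, and both were hybridised together to a cDNA array of 6912 spots. The series held 3 such hybridizations from independent biological samples, and each array was scanned at high and at low laser power, which gave 6 scans of 3 replicates. High-power scans held values for 5737, 5243 and 4693 spots in replicates 1, 2 and 3, and low-power scans for 2465, 1789 and 3372. Both scans of an array were averaged, and 4312 genes had a value in all 3 replicates. Ratios are given as treated over untreated, the likely direction from the dye of each channel, because the deposited values do not state it. If the ratio ran the other way, every "higher" and "lower" would be exchanged. No array with exchanged dyes was part of the series, so dye and treatment could not be told apart. The compound was dissolved in dimethyl sulfoxide and the control was labelled as untreated, so the solvent could not be told apart from the compound either.

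The first comparison asked which transcripts differed between cells exposed to zinc pyrithione and untreated cells. Genes of iron acquisition stood at the top: FIT1 (YDR534C), which encodes a cell wall mannoprotein that helps retain siderophore-bound iron, was 82.6-fold higher in treated cells, with a log2 ratio of 6.37 ± 0.63 (SD, n = 3; limma adjusted p = 2.9e-05). ARN2 (YHL047C), a siderophore transporter gene, was 35.1-fold higher at 5.13 ± 0.57 (limma adjusted p = 4.5e-05). At the other end, SDH3 (YKL141W), which encodes a membrane subunit of succinate dehydrogenase, was 12.5-fold lower at -3.65 ± 0.17 (limma adjusted p = 4.5e-05). CTT1 (YGR088W), the gene of the heme-containing cytosolic catalase, was 10.4-fold lower at -3.38 ± 0.66 (limma adjusted p = 0.00025).

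Of the 4312 genes tested, 350 were higher and 414 lower in treated cells at a limma adjusted p under 0.05, which together is 17.7% of the genes. Of these, 119 were higher and 166 lower by 2-fold or more. The 12 highest genes also included the iron genes FIT2, FIT3, ARN1, HMX1, FRE2 and SIT1, described below. The remaining 4 were PDR5, a multidrug efflux pump gene, MET17, which encodes the enzyme that fixes sulfide into homocysteine, HUG1, a small gene induced by DNA damage, and GTT2, a glutathione transferase gene. Among the 12 lowest, SDH2, SDH4, CYT1, QCR7, COX4 and COX6 belong to the respiratory chain, and IRC7 (-2.80 ± 0.23) and REE1 (-2.55 ± 0.42) to the list of copper uptake genes. KTR6 (YPL053C), a mannosylphosphate transferase gene, stood at -2.69 ± 0.51 and YPQ1 (YOL092W), which encodes a vacuolar basic amino acid transporter, at -2.53 ± 0.26 (limma adjusted p = 0.00035 and 0.00018). Across genes, which are not independent replicates, log2 ratios of replicate pairs correlated with Pearson's r of 0.716, 0.673 and 0.65. All 764 called genes had the same sign in all 3 replicates, which a call on 3 arrays largely presupposes. Of all 4312 genes tested, 54.9% had the same sign in all 3, where chance alone gives 25%. The counts of called genes were 132 higher and 176 lower without replicate 1, and 135 higher and 179 lower without replicate 2.

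**Figure D1:**
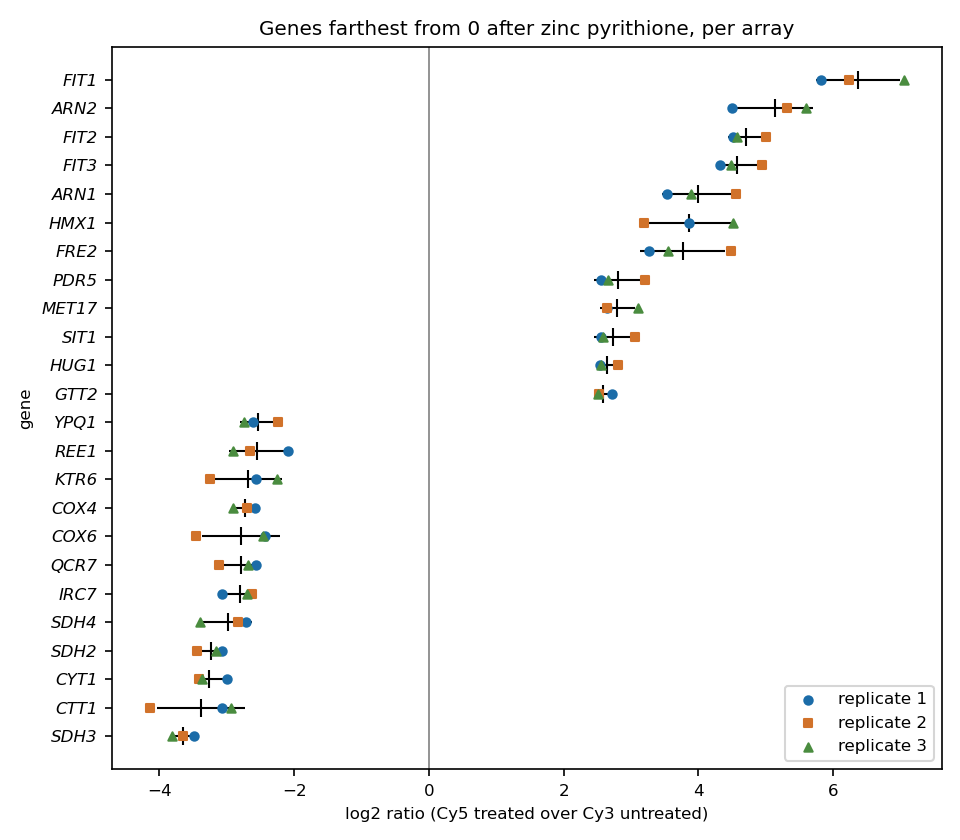
Log2 ratio of treated over untreated cells (horizontal axis) for the 12 highest and the 12 lowest genes past the threshold (vertical axis), with a point for each of 3 replicates and a black bar for their mean and SD. FIT1 is highest at a mean of 6.37 and SDH3 lowest at -3.65. The replicates of each gene lie on one side of 0, as the rule for choosing these genes requires.

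Siderophore and cell wall iron genes were all positive in treated cells. Of the 7 genes on this list, 6 rose, and 7 did when adjusted over the list alone, with a median log2 ratio of 4.58 (limma's fry adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation). Besides FIT1 and ARN2, FIT2 stood at 4.70 ± 0.27, FIT3 at 4.58 ± 0.32, ARN1 at 3.99 ± 0.52 and SIT1 at 2.73 ± 0.28, where the FIT genes encode cell wall mannoproteins and the others siderophore transporters. ENB1, the enterobactin transporter gene, had a log2 ratio of 1.32 ± 1.17 (limma adjusted p = 0.053). Of 13 genes of reductive and vacuolar iron transport, 10 rose and 2 fell, with 10 and 2 also when adjusted over the list alone, and the median was 1.42 (fry adjusted p = 0.015; adjusted p = 0.29 with an estimated correlation). FRE2, a ferric reductase gene, was highest among them at 3.76 ± 0.63. FET3 and FTR1, the ferroxidase and the permease of the high-affinity iron uptake system, stood at 2.20 ± 0.59 and 2.19 ± 0.05. FRE3 (2.01 ± 0.24), FRE6 (1.07 ± 0.23) and FRE5 (0.79 ± 0.11), further reductase genes, rose as well. So did ATX1 (1.60 ± 0.33) and CCC2 (1.58 ± 0.13), which deliver copper to the ferroxidase, and FET5 (1.42 ± 0.12) and FTH1 (1.11 ± 0.68) of the vacuolar membrane. FRE1 (-2.37 ± 0.84), a reductase gene also placed on the copper uptake list, and SMF3 (-0.79 ± 0.12), a vacuolar iron transporter gene, were the 2 that fell. FRE4 had a log2 ratio of 0.31 ± 0.45 (limma adjusted p = 0.31).

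Of 8 measured intracellular members of the iron regulon, 6 rose, and 6 did when adjusted over the list alone, with a median of 1.74 (fry adjusted p = 0.0089; adjusted p = 0.29 with an estimated correlation). HMX1, the heme oxygenase gene, stood at 3.85 ± 0.66 (limma adjusted p = 0.00018). TIS11 (1.91 ± 0.20) encodes an RNA-binding protein that promotes decay of transcripts of iron-using proteins, and ISU2 (1.87 ± 0.27) a scaffold for iron-sulfur cluster assembly. AKR1 (1.83 ± 0.29), BIO5 (1.64 ± 0.91), which encodes a transporter of biotin precursors, and COT1 (1.45 ± 0.29), a vacuolar zinc and cobalt transporter gene, rose too. ISU1 at -0.0041 ± 0.42 (limma adjusted p = 0.99) and PCL5 at -0.34 ± 0.07 (limma adjusted p = 0.16) were not past the threshold. Over the 3 iron lists together, 22 of 28 measured genes rose and 2 fell. Several of these genes belong to families of related sequence, for which a cDNA spot can bind more than one transcript. BIO5 was also the sole measured gene of the biotin list, which was therefore not tested as a list.

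Genes of enzymes that use iron were lower in treated cells. Of 14 measured iron-dependent enzyme genes, 9 fell and 0 rose, against 10 and 1 when adjusted over the list alone, with a median of -1.31 (fry adjusted p = 0.00044; adjusted p = 0.29 with an estimated correlation). CTT1 and SDH2 were lowest, the latter at -3.23 ± 0.19. ERG11 (-2.37 ± 0.07) encodes a heme-dependent sterol demethylase and SCS7 (-2.35 ± 0.19) a sphingolipid hydroxylase. In heme biosynthesis, 3 of 6 measured genes fell, and 3 did when adjusted over the list alone, with a median of -0.50 (fry adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation). HEM1, which encodes the enzyme of the first step, stood at -1.50 ± 0.21, HEM3 at -1.21 ± 0.15 and HEM4 at -0.70 ± 0.28. Of 14 measured genes of iron-sulfur cluster assembly, 1 rose and 2 fell, against 2 and 3 when adjusted over the list alone, and the list was not past the threshold (fry adjusted p = 0.39). NFS1, the cysteine desulfurase gene, rose to 0.82 ± 0.30, whereas GRX5 (-1.82 ± 0.31) and NFU1 (-1.72 ± 0.11), which act late in the pathway, fell. The median of this list, 0.15, had the opposite sign to its mean and its test.

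Nuclear genes of the respiratory chain were lower in treated cells. Of 17 measured, 16 fell, and 16 did when adjusted over the list alone, with a median of -2.20 (fry adjusted p = 0.0073; adjusted p = 0.29 with an estimated correlation). The lowest 4 were SDH3, CYT1 (-3.26 ± 0.23), which encodes the heme-bearing cytochrome subunit of complex III, SDH2 and SDH4 (-2.98 ± 0.37). QCR7 of complex III stood at -2.79 ± 0.29, and COX6 and COX4 of cytochrome c oxidase at -2.78 ± 0.58 and -2.73 ± 0.16. In the TCA cycle, 8 of 13 measured genes fell and 0 rose, against 8 and 2 when adjusted over the list alone, with a median of -1.12 (fry adjusted p = 0.0055; adjusted p = 0.29 with an estimated correlation). Besides SDH2, SDH3 and SDH4, which are on this list and on that of the respiratory chain, the farthest from 0 was ACO1 at -1.93 ± 0.13, the gene of the iron-sulfur enzyme aconitase. Of 11 measured ATP synthase genes, 3 fell, and 6 did when adjusted over the list alone, with a median of -0.48 (fry adjusted p = 0.053). ATP17 (-0.83 ± 0.31), ATP3 (-0.81 ± 0.32) and ATP16 (-0.72 ± 0.38) were those 3. Centring each scan on its median, or each block of spots, took this list past the threshold, at fry adjusted p = 0.048 and 0.044 (adjusted p = 0.36 with an estimated correlation). Glycolysis and fermentation genes had a median of 0.21, with 2 of 16 measured genes higher and 1 when adjusted over the list alone (fry adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation). GPM1 stood at 0.74 ± 0.13 and PDC5 at 0.64 ± 0.31. Centring each scan or each block ended the call of this list (fry adjusted p = 0.062 and 0.074) and of PDC5 (limma adjusted p = 0.059 and 0.069), which also lost its call with quantile normalization (0.053).

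All 3 measured genes of the copper uptake list fell, and 3 did when adjusted over the list alone. The median was -2.55 (fry adjusted p = 0.0073, and camera adjusted p = 0.29 with an estimated correlation). These 3 were IRC7, REE1 and FRE1, all targets of the copper-sensing activator Mac1. CTR1, CTR3 and FRE7 of the list had values on 2 arrays and were not tested. Of 4 copper detoxification genes, 3 rose, and 4 did when adjusted over the list alone, but the list was not past the threshold (median 0.73; fry adjusted p = 0.084). CRS5 (0.97 ± 0.55) and CUP1-1 (0.66 ± 0.26) encode metallothioneins and SOD1 (0.80 ± 0.40) the copper and zinc superoxide dismutase. CUP1-1 shares its sequence with its neighbouring copy. The call of CUP1-1 ended in the high-power and in the low-power scans alone and with centred blocks (limma adjusted p = 0.054, 0.078 and 0.079). That of SOD1 ended in the low-power scans alone, where CRS5 was not tested. Of 13 measured zinc regulon genes, 2 rose and 3 fell, against 3 and 5 when adjusted over the list alone, with a median of -0.14 (fry adjusted p = 0.046, toward lower; adjusted p = 0.53 with an estimated correlation). The call of this list ended in the high-power scans alone (fry adjusted p = 0.054). ZRT1 (-1.83 ± 0.68) and ZRT2 (-0.68 ± 0.22), the zinc importer genes of the plasma membrane, fell, and so did the peroxiredoxin gene TSA1 (-2.11 ± 0.43), whereas ZRT3 (1.09 ± 0.03), which encodes a vacuolar zinc exporter, rose.

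Multidrug resistance genes were higher in treated cells. Of 10 measured, 7 rose, and 8 did when adjusted over the list alone, with a median of 0.83 (fry adjusted p = 0.0045; adjusted p = 0.29 with an estimated correlation). PDR5 stood at 2.80 ± 0.35, ICT1, a lipid acyltransferase gene, at 1.81 ± 0.01, PDR16, a phosphatidylinositol transfer protein gene, at 1.16 ± 0.30 and the hexose transporter gene HXT9 at 0.97 ± 0.09. Oxidative stress genes went both ways: 7 of 17 measured rose and 3 fell, against 8 and 4 when adjusted over the list alone, and the list was not past the threshold (median 0.50; fry adjusted p = 0.061). GTT2 (2.59 ± 0.12) and OYE3 (2.43 ± 0.33), an NADPH oxidoreductase gene, were higher, while CTT1 and TSA1 were lower. Of 3 measured aryl-alcohol dehydrogenase genes, 2 rose, and 3 did when adjusted over the list alone (median 0.68; fry adjusted p = 0.084). AAD14 stood at 0.75 ± 0.29 and AAD4 at 0.68 ± 0.35, and centring each scan ended the call of AAD4 (limma adjusted p = 0.052). Among 8 measured DNA damage genes, 5 rose and 2 fell, with 5 and 2 also when adjusted over the list alone (median 0.69; fry adjusted p = 0.059). HUG1 stood at 2.64 ± 0.15 and DDR48 at 1.64 ± 0.50, whereas RNR4 (-1.47 ± 0.08) and RNR2 (-0.97 ± 0.15), which encode the small subunits of the iron-containing ribonucleotide reductase, fell.

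Of 23 measured heat shock chaperone genes, 10 fell and 1 rose, against 13 and 1 when adjusted over the list alone, with a median of -0.65 (fry adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation). BTN2 (-1.43 ± 0.44), YDJ1 (-1.26 ± 0.50), an Hsp40 co-chaperone gene, and SSC1 (-1.25 ± 0.34), the mitochondrial Hsp70 gene, fell, and the small heat shock protein gene HSP26 rose to 2.32 ± 0.35. Of 24 measured general stress genes, 3 rose and 2 fell, with 3 and 2 also when adjusted over the list alone (median -0.04; fry adjusted p = 0.77). GRE1 (1.79 ± 0.31) and TFS1 (0.85 ± 0.38) rose, while CTT1 and UGP1 (-1.44 ± 0.21) fell. Proteasome genes had a median of 0.21 and were not past the threshold as a list (fry adjusted p = 0.09), with 4 of 41 measured genes higher and 4 when adjusted over the list alone. RPT1 (0.89 ± 0.05) and RPN6 (0.72 ± 0.31) of the regulatory particle, UFD1 (0.65 ± 0.09) and PRE1 (0.64 ± 0.19) were the 4. In the unfolded protein response list, 1 of 9 measured genes rose and 1 fell, and 1 and 1 did when adjusted over the list alone (median 0.26; fry adjusted p = 0.15). LHS1 stood at 0.58 ± 0.20 and HAC1 at -0.59 ± 0.17. The call of LHS1 ended in the high-power and in the low-power scans alone, and with centred scans or blocks (limma adjusted p = 0.073, 0.06, 0.059 and 0.109). In the cell wall integrity list, HSP150 rose to 0.64 ± 0.03 and CHS3, a chitin synthase gene, fell to -0.86 ± 0.08, the 2 of 13 measured genes past the threshold, and 1 and 1 were past it when adjusted over the list alone (median -0.34; fry adjusted p = 0.22).

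Cytosolic ribosomal protein genes had a median of -0.39, with 23 of 117 measured genes lower and 0 higher, and 35 lower when adjusted over the list alone. As a list they were not past the threshold (fry adjusted p = 0.085), and they were when set against the other genes with a preset correlation (camera adjusted p = 8.4e-11; adjusted p = 0.36 with an estimated correlation). RPS12 (-1.34 ± 0.49), RPS20 (-1.01 ± 0.36), RPL24A (-0.96 ± 0.32) and RPL23A (-0.94 ± 0.25) were farthest from 0, and the last 2 have near-identical paralogs. Ribosome biogenesis genes had a median of -0.42, with 7 of 29 measured lower and 0 higher, against 10 and 2 when adjusted over the list alone (fry adjusted p = 0.11). NOP1 stood at -1.24 ± 0.32, DBP3 at -1.20 ± 0.28, RPA34 at -1.06 ± 0.53 and NSR1 at -1.02 ± 0.29. Of 28 measured amino acid biosynthesis genes, 3 rose and 9 fell, against 3 and 10 when adjusted over the list alone, with a median of -0.25 (fry adjusted p = 0.035; adjusted p = 0.36 with an estimated correlation). LYS9 (-1.47 ± 0.25), ARO3 (-1.44 ± 0.31) and ILV2 (-1.21 ± 0.26) fell, and LEU2 (1.55 ± 0.63) rose. Sulfate assimilation and methionine genes had a median of 0.32, with 3 of 17 measured higher and 1 lower, and 3 and 1 when adjusted over the list alone (fry adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation). MET17 stood at 2.80 ± 0.26, the methionine permease gene MUP1 at 1.40 ± 0.33 and CYS3 at 0.87 ± 0.14, whereas MET5, which encodes a subunit of the iron-containing sulfite reductase, fell to -0.90 ± 0.47.

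Of 14 phosphate genes, 7 rose and 2 fell, against 8 and 2 when adjusted over the list alone, and the list was not past the threshold (median 0.80; fry adjusted p = 0.084). PHO12 (1.76 ± 0.04), PHO11 (1.53 ± 0.52) and PHO5 (1.32 ± 0.77) encode secreted acid phosphatases of related sequence, near-identical for PHO11 and PHO12. PHM6 stood at 1.47 ± 0.10. Ergosterol genes split, with 3 of 23 measured higher and 3 lower, against 5 and 3 when adjusted over the list alone. ERG6 rose to 1.35 ± 0.27, while ERG11, ERG1 (-2.04 ± 0.11), the squalene epoxidase gene, and ERG7 (-1.82 ± 0.24) fell. The list median of 0.07 had the opposite sign to the mean and to the test (fry adjusted p = 0.21, toward lower). In the hypoxic list, TIR1 rose to 0.95 ± 0.02 and ANB1 fell to -1.34 ± 0.61, the 2 of 11 measured genes past the threshold, and 2 higher and 2 lower were past it when adjusted over the list alone (median 0.18; fry adjusted p = 0.64). None of 7 measured histone genes was past the threshold, and 0 were when adjusted over the list alone (median -0.33; fry adjusted p = 0.22). HHF1 and HHF2 had log2 ratios of -0.53 ± 0.21 and -0.48 ± 0.24.

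Marker lists of other cell types and states were measured as well. Neither STE6 of the a-cell list (1.04 ± 2.07, limma adjusted p = 0.29), the sole member measured on all arrays, nor any of 3 alpha-cell genes was past the threshold, and 0 were when adjusted over each list alone (alpha-cell median 0.03; fry adjusted p = 0.56). SAG1 and STE3 of the alpha-cell list had log2 ratios of 0.67 ± 0.97 and 0.03 ± 0.07. Of 5 measured meiosis and sporulation genes, 2 rose, and 2 did when adjusted over the list alone, with a median of 0.20 (fry adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation). These were SPS100 (2.30 ± 0.27), a spore wall gene, and DMC1 (0.64 ± 0.27), a meiotic recombinase gene. Of 7 measured stationary phase genes, 3 rose, against 5 higher and 1 lower when adjusted over the list alone, with a median of 0.65 (fry adjusted p = 0.031; adjusted p = 0.36 with an estimated correlation). GRE1, SNZ2 (0.66 ± 0.15) and SNO2 (0.65 ± 0.30) were those 3, and centring each scan ended the call of SNO2 (limma adjusted p = 0.052).

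**Figure D2:**
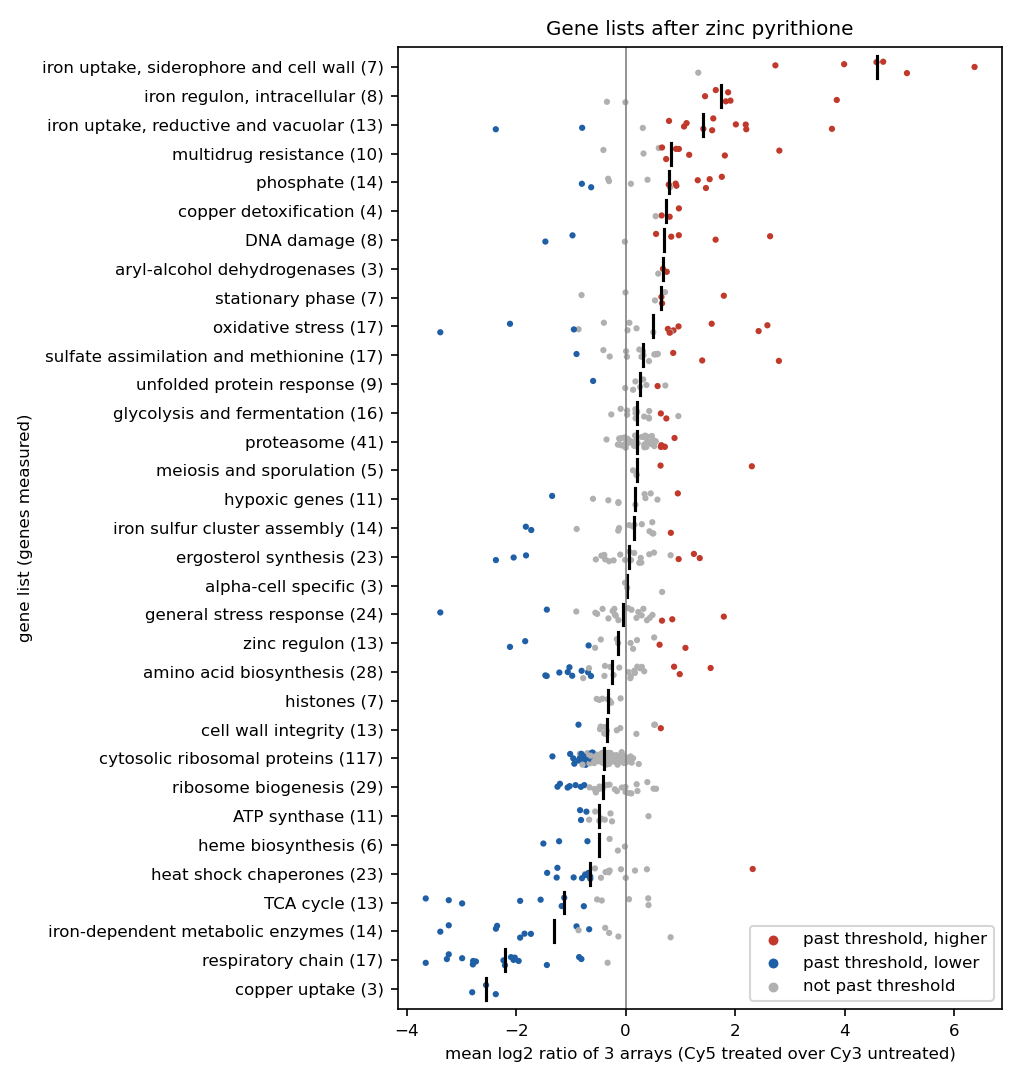
Mean log2 ratio of treated over untreated cells over 3 replicates (horizontal axis) for each measured member of the 33 tested gene lists (vertical axis, number of measured genes in brackets). Points are genes, red where higher and blue where lower past the threshold and grey otherwise. Black bars are list medians, from 4.58 for siderophore and cell wall iron genes to -2.55 for the copper uptake list.

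Of the 33 lists tested, 16 were past the threshold with limma's fry, 8 toward higher and 8 toward lower. With limma's camera at a preset correlation 21 lists were past it, 14 of them shared with fry. The zinc regulon and amino acid biosynthesis lists, called by fry, were not (camera adjusted p = 0.44 and 0.051). Camera alone called 7 lists. Besides cytosolic ribosomal proteins these were ATP synthase (0.0045), ribosome biogenesis (0.0053), proteasome (0.0087) and phosphate (0.011). Copper detoxification (0.015) and aryl-alcohol dehydrogenases (0.035) were the others. With an estimated correlation 0 lists were past the threshold, the smallest adjusted p being 0.29. Without replicate 1, 3 lists were past the threshold under fry, those of iron-dependent enzymes and multidrug resistance and, newly, ATP synthase. Without replicate 2 or 3, 0 were. These tests had 2 arrays each, so a lost call cannot tell fewer arrays from disagreement between replicates. In replicates 1, 2 and 3 the siderophore list had medians of 4.32, 4.94 and 4.48. The respiratory chain had -2.31, -2.39 and -2.30, while the meiosis and sporulation list had 0.38, 0.63 and -0.01. In the low-power scans alone the lists of the zinc regulon, multidrug resistance, heat shock chaperones, sulfate assimilation and methionine, amino acid biosynthesis, and glycolysis and fermentation lost their call (fry adjusted p = 0.098, 0.54, 0.093, 0.061, 0.22 and 0.071), and the proteasome list was past the threshold (0.014). Of the 122 genes chosen by the rule for named genes, 114 had values in all 3 high-power scans, ARN2, FIT2, SIT1, FET3 and PDR5 not among them. Where a gene lacked a high-power value on an array, the low-power value alone was used. In all 3 low-power scans 48 of the 122 had values, FIT1, ARN2, SDH3 and CYT1 not among them. Of these 48, 14 lost their call in those scans alone. Without replicate 1, 2 and 3, 33, 32 and 15 of the 122 lost it. Among the iron genes the latter were BIO5, FRE5 and SMF3 without replicate 1 or 2 and FTH1 without replicate 2 or 3.

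The second comparison set the high-power against the low-power scan of the same array, to show how far laser power shapes the ratio. None of the 1372 genes with both scans on all 3 arrays differed between scans with limma (smallest adjusted p = 0.838), and 46 had an unadjusted p under 0.05, where chance alone gives 68.6. On 3 arrays small differences can be missed. FIT1, FIT2, ARN2, SIT1, FET3, PDR5, SDH3 and CYT1 lacked values in some scans and lay outside this test. Of the siderophore list it held 1 gene, ENB1, at 1.69 in the high-power and 0.96 in the low-power scans. Log2 ratios of both scans correlated across genes with Pearson's r of 0.844, 0.846 and 0.813 in replicates 1, 2 and 3, over 2293, 1691 and 3213 genes. The SD of the difference between scans across genes was 0.331, 0.381 and 0.418 on the log2 scale. Log2 ratios spread more widely in the low-power scans, with SDs across those genes of 0.616, 0.713 and 0.718 against 0.541, 0.63 and 0.579 in the high-power scans.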

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

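The test of spots without a gene name was chosen only after the data were seen.

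Spots that the annotation used here does not name lie outside the comparisons, and they also held signal. Of 149 such spots with values in all 3 replicates, 15 (10.1%) were past a limma adjusted p of 0.05 when fitted together with the named genes. Of these 15, 8 were higher and 7 lower in treated cells, with log2 ratios up to 2.24 and down to -1.25. In the same fit 335 of the 4312 named genes were higher and 406 lower. In the reported fit, without these spots, 17.7% of the named genes were called. No explanation was tested, and the genes of these spots are not analysed here.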

How the results depend on the processing

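Centring of blocks, the unnamed spots included and the lowest values taken as missing were chosen only after the data were seen; the other settings were fixed before.

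No gene called in both the reported analysis and an alternative had opposite signs in them. The counts of 350 higher and 414 lower genes fell to 74 and 77 in the low-power scans alone (1429 genes tested, which held 289 of the reported 764 calls); fewer genes tested is thus not the whole reason, and the rest of the cause was not tested. Over genes with both scans on all arrays they were 175 and 182 (1372 tested), of which 123 and 143 were among the 266 reported calls in these genes, so that within them more were called. They were 65 and 77 with treat at 1.5-fold and 132 and 163 at an adjusted p under 0.01, both stricter by construction. With 2-fold in all 3 replicates without a test they were 72 and 88, all among the reported calls. That rule asks for a size that a reported call need not reach, and 119 and 166 of the reported calls reached it on average. Leaving out a replicate gave 132 to 297 higher and 176 to 337 lower genes, with fewer samples. In the high-power scans alone 515 and 570 genes were called, 324 and 404 of them shared with the reported calls; the cause was not tested. Centring each scan gave 303 and 486, centring each block 336 and 492. The other settings (quantile normalization, at least 2 replicates, robust eBayes, lowest values missing, unnamed spots included) gave 328 to 357 higher and 402 to 418 lower, and of the named genes PDC5 lost its call with quantile normalization. No scaling moved the median of all genes by over 0.1. ENB1 was past the threshold in the high-power scans alone (1.69, limma adjusted p = 0.0033) and with centred blocks (limma adjusted p = 0.049). SAG1 and both histone genes named in the report were past it in the high-power scans alone, and HHF1 also with centred scans. Of 122 named genes 48 had values in all 3 low-power scans, and 14 lost their call there: ATP3, ATP16, ATP17, CUP1-1, GPM1, HSP150, LHS1, PDC5, PHO5, RPN6, SOD1, TFS1, YDJ1 and ZRT2. Of all 122, 33, 32 and 15 lost it without replicate 1, 2 and 3, all with the same direction. None of the 1372 genes with both scans on all arrays differed between scan powers with centred scans or with a replicate left out.

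The 16 lists past the threshold became 6 of 24 testable in the low-power scans alone. With a replicate left out, and thus 2 arrays per test, 0 to 3 were past it (2 of the 16 and ATP synthase without replicate 1). Under camera with an estimated correlation 0 were. That setting also missed the list shifted by -1 in simulated data, where genes were drawn independently. On 3 arrays it leaves few degrees of freedom, and the siderophore list, with a median of 4.58, also had no call. The lack of a call in this setting thus cannot decide for or against a list. How often it would miss shifts of the size seen here is not known. With a replicate left out, the fry adjusted p ranged from 0.0672 to 0.121 for siderophore and cell wall iron genes, 0.0624 to 0.166 for reductive and vacuolar iron genes, 0.0516 to 0.121 for the intracellular iron regulon, 0.0491 to 0.0856 for iron-dependent enzymes, 0.0672 to 0.0907 for the TCA cycle and 0.0602 to 0.118 for the respiratory chain, all in the same direction. With an estimated correlation the adjusted p was 0.361 for the siderophore list and 0.289 for the other 5 of these. In the low-power scans alone the siderophore list had too few genes for a value. In the high-power scans alone it was tested on 4 of its 7 genes (fry adjusted p = 0.015). Signal over background was not analysed here, and missing values in the low-power scans limit what those scans can show.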

Other observations

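The tests of gene families, of cross-hybridization, of centred blocks, and the permutation of the respiratory chain and ATP synthase genes were chosen only after the results were seen, as were IZH1 and the genes singled out in the first 2 paragraphs.

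Of 52 measured genes with symbols MRP, MRPL, MRPS or RSM, most of which encode mitochondrial ribosomal proteins, 28 fell and 0 rose, with a median log2 ratio of -0.65; the 52 genes were not tested as a set. The median stayed between -0.65 and -0.71 with centred scans, quantile normalization or centred blocks. All 4 prefixes were past the threshold under limma's camera with a preset correlation (adjusted p from 1.4e-08 to 0.022) and none with an estimated correlation (adjusted p = 0.9), while fry called the 7 MRPS genes (adjusted p = 0.048) and not MRPL, RSM or MRP (0.077, 0.087 and 0.055). They were among 146 groups of genes sharing a symbol prefix, of which 18 were past the threshold under camera and 0 with an estimated correlation. Of 13 genes with the symbol TIM, most of them of mitochondrial protein import but with TIM11 of the ATP synthase among them, 4 fell (median -0.50). With centred blocks 6 of the TIM genes fell (median -0.54). Of 18 PAU genes, a family of near-identical cell wall protein genes whose transcripts a cDNA spot cannot separate, 7 rose, and 6 did with centred scans or quantile normalization (median 0.68).

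Genes measured on 2 of the arrays were left out of the reported counts. Of 736 such genes, 29 were higher and 50 lower when 2 replicates sufficed. All 5 such genes of the respiratory chain list and all 3 of the iron-dependent enzyme list were among the lower, such as RIP1 (-2.95), the Rieske iron-sulfur protein gene, CYC1 (-2.58), the cytochrome c gene, and CCP1 (-3.01), the cytochrome c peroxidase gene (limma adjusted p = 0.00094, 0.00075 and 0.00049). Both such heme biosynthesis genes, HEM13 (-2.30) and HEM15 (-2.22), were lower too (limma adjusted p = 0.0019 and 0.0012). Of 3 such genes of iron-sulfur cluster assembly, YFH1 (-1.74) and ISA1 (-1.73) were lower (limma adjusted p = 0.0036 and 0.0037). MET14 (-2.09), 1 of 4 such genes of the sulfate assimilation and methionine list, was lower against the direction of that list (limma adjusted p = 0.0017). Neither of the 2 such genes of the intracellular iron regulon list, MRS4 (0.29) and VHT1 (0.28), was past the threshold (limma adjusted p = 0.45 for each). Among genes on all arrays outside the lists, CTH1, the relative of TIS11, stood at -1.75 ± 0.26 against the rise of TIS11, and CCC1, the gene of the vacuolar iron importer, at -2.12 ± 0.49 (limma adjusted p = 0.0007 and 0.00079).

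For the 764 genes called, the signs of the 3 arrays were turned in each of the 4 distinct patterns; 1 pattern, the real one, gave as many calls, and the highest of the other patterns gave 0. The 4 patterns are too few for a share under 0.05, the smallest possible being 0.25.

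A first pattern is the rise of the iron genes. HMX1, ATX1 and CCC2, taken to have no close relative in the yeast genome, had a median log2 ratio of 1.60, each past the threshold. They were picked after their values were known, so they cannot decide on cross-hybridization between related genes. It stays open for the other iron genes. A shift shared by a whole block of spots, those with the same first digit in the spot number, is argued against as the whole cause. The median of the 3 iron lists was 1.68 after each block was centred. Position effects on a finer scale are not removed by this centring and stay open. Dye bias stays open and cannot be told apart from the treatment, because 0 arrays had the dyes exchanged. Beside these open causes, a response of the cells to zinc pyrithione or to its solvent, such as to low available iron, may be a candidate explanation. It was not tested.

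A second pattern is that the 3 tested genes of the copper uptake list were lower and 3 of 4 copper detoxification genes higher. The zinc importer genes ZRT1 and ZRT2 were lower, while ZRT3 (1.09) and IZH1 (0.62) of the zinc regulon list were higher (limma adjusted p = 0.0036 and 0.035). If the cells held more copper, the copper uptake genes left out for missing values were predicted to be below 0 on every array that measured them, and 2 of 3 were: CTR1 at -3.88 and FRE7 at -3.65, but CTR3 at 0.60. CTR3, above 0 on both arrays (0.47 and 0.74, SD 0.19), met the bound set in advance against more copper, but that bound was wrong for this strain: the S288C reference lists the transposon genes YLR410W-A and YLR410W-B directly upstream of CTR3, whose promoter is known to be interrupted there, a reason raised only after the value was seen. If the cells held more zinc, most of the zinc regulon genes left out were predicted below 0, and 3 of 5 were. Those below 0 were ADH4 at -2.67, RTC4 at -0.45 and ZAP1 at -0.36, while VEL1 stood at 0.37 and NRG2 at 0.02. Chance gives this count with an exact binomial p of 0.5 (one-sided), which takes the genes as independent and ignores their sizes. Of the 5, ADH4 alone was past the threshold when 2 replicates sufficed (limma adjusted p = 0.0023). More copper and more zinc both stay open, since the genes left are too few to decide either, and the metal content of the cells is not part of these data.

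The third pattern is that the respiratory chain list was lower than the ATP synthase list. The medians of 17 and 11 genes differed by -1.72; the permutation p of 0.0073 (two-sided, 100000 resamples across genes, which are not independent replicates) describes this same difference and is no separate evidence for it. Scan power as the cause is argued against by a difference of -1.76 in the high-power scans alone and -1.56 in the low-power scans alone, the latter over 4 and 8 genes. Dye bias was not tested here and stays open. No biological explanation was tested.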
